A study of Saccharolobus islandicus REY15A with 12 samples.

How the data were processed

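The series holds 12 RNA-seq libraries of Saccharolobus islandicus REY15A, 2 for each combination of 3 hosts and 2 plasmids, and groups were taken from the sample labels. Per the labels' protocols, rRNA was removed, libraries were made with dUTP second-strand marking, and cells were harvested at an OD600 of 0.3. Whether strand was used in counting is not given in the sources used here. The submitters' processing notes name CASAVA, Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0, without giving their roles. The genome build and the annotation are not given in the sources used here, so no coordinates are printed.

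The authors deposited FPKM values (fragments scaled by feature length and by the reads counted in the library) in 3 tables, 1 per host. The wild-type table has 2829 features including rRNA, tRNA and ncRNA, and 2713 are listed for each deletion strain, including plasmid genes and unidentified features without a locus tag; 2644 are shared. Because each table was scaled over its own features, levels were tested only within a table. The planned contrasts of each deletion strain with wild type under pSeSD were therefore not run, and levels of different hosts stand side by side only as separately normalized values. The authors also deposited tables of called genes with mean read counts divided by size factors (a signal, not whole counts), a ratio of these as log2 fold change, and p-values. These are quoted as the authors' own. Features without a locus tag were kept apart between wild type and the deletion strains, since their numbering belongs to different feature sets. The mean counts in the authors' deposited table for the cas1 deletion were not used, because their headers do not match the groups of that comparison.

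Gene symbols and coding lengths came from RefSeq assembly ASM18955v1, matched by locus tag for 2600 of 2695 tags. Symbols cover 375 features and 1212 have product names from the authors' deposited tables, together 1398. As those tables list only called genes, lists built on product names are partly chosen on these samples. The plasmid features csa3a, pyrE, repA, copG and ampR are at 0 in every deletion library.

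FPKM times coding length comes in whole multiples of 1 step per library, which gives the number of reads counted, 2370921 to 3862831 per library. With RefSeq lengths 92.5% to 93.3% of genes came out as whole reads within 0.01. For 182 genes, among them cas1 and csa3a, another length was recovered as the multiple of 3 nearest to the RefSeq length that gave whole reads in every library above 0, with at least 6 such libraries; 27 genes kept no whole reads in some library and their reads were treated as missing. Ratios of pooled reads carry exact Clopper-Pearson 95% intervals, and a group at 0 was set to a floor of 3 reads over the group. Intervals and floors cover counting error only.

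The main test was limma 3.58.1 in R 4.3.3 (eBayes with trend, 2-sided) on log2(FPKM + 1), with 6 group means and 1 shared spread over the 12 libraries, after a filter at a mean of 1 FPKM, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are on this scale, which understates changes of low genes. Differences between hosts were tested as interaction contrasts. Gene lists were keyword patterns and were tested with limma's camera at its preset correlation against 1381 genes with a name. On simulated data with 200 changed genes, 2-fold changes were recovered in 92% of cases for wild type, 77% for the cas1-deletion comparison and 89% for the triple deletion, and 4-fold changes in 97%, 95% and 98%. The simulation gave each gene the same spread in all 6 groups. The triple-deletion pSeSD pair varied more than the others (chi-square per degree of freedom 54.2), so recovery in that host may be overstated. Tables were made with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.

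The samples, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes csa3a, cas1, cas3 and both cmr2 genes first, then per host the 10 highest and 10 lowest fold changes among genes past the threshold with separated libraries and a mean of at least 10 FPKM, the CRISPR genes, up to 4 members of each other list, up to 5 per direction for each difference between hosts and for the mean, and the 3 largest and 3 smallest fold changes of each authors' deposited table. Genes named beyond it were chosen after their values were seen. The alternatives were pseudocounts of 0.1 and 10, no filter and a filter at 10 FPKM, centring on the library median, quantile normalization, a fit on the compared groups alone, eBayes without trend, a replicate block and leaving out each library. Rescaling over shared features, limma-voom on recovered reads and a mean without the cas1-deletion comparison were chosen after seeing the data.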

Results

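Transcript levels were measured by rRNA-depleted RNA-seq in 12 libraries of Saccharolobus islandicus REY15A, a thermoacidophilic archaeon, grown at 78 °C to log phase (OD600 of 0.3). Csa3a is a DNA-binding regulator encoded beside the adaptation genes of the type I-A CRISPR-Cas locus, and the series asks which genes respond when it is overexpressed. Each of 3 hosts carried either the Csa3a expression plasmid pCsa3a or the empty plasmid pSeSD, with 2 libraries per group. The hosts were the wild type, a strain labelled as a cas1 deletion, and a strain lacking cas3 and both cmr2 genes (cmr2-alpha and cmr2-beta), called the triple deletion here. Between 2370921 and 3862831 reads were counted per library. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

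The targeted genes were examined first in every group. csa3a (SiRe_0764, RefSeq symbol csa3) rose from 47.0 ± 1.13 to 14580 ± 336 FPKM in wild type (SD, n = 2 per group), from 10.9 ± 2.49 to 12070 ± 331 FPKM in the cas1-deletion comparison and from 30.5 ± 17.4 to 13740 ± 1325 FPKM in the triple deletion. Reads of the plasmid copy and of the chromosomal copy cannot be separated in these values. cas3 (SiRe_0769) and both cmr2 genes (SiRe_0598 and SiRe_0894, RefSeq symbol cas10) were at 0 reads in all 4 triple-deletion libraries. cas1 (SiRe_0761) was at 0 reads in both libraries labelled cas1 deletion with pCsa3a. In the 2 libraries labelled cas1 deletion with pSeSD, however, cas1 had 62 and 45 reads (22.5 and 15.9 FPKM), while the wild-type pSeSD libraries had 7.7 and 12.5 FPKM in a separately normalized table. The cas1 values therefore go against the label of these 2 libraries, and every direction drawn in the cas1-deletion comparison rests on them.

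**Figure D1:**
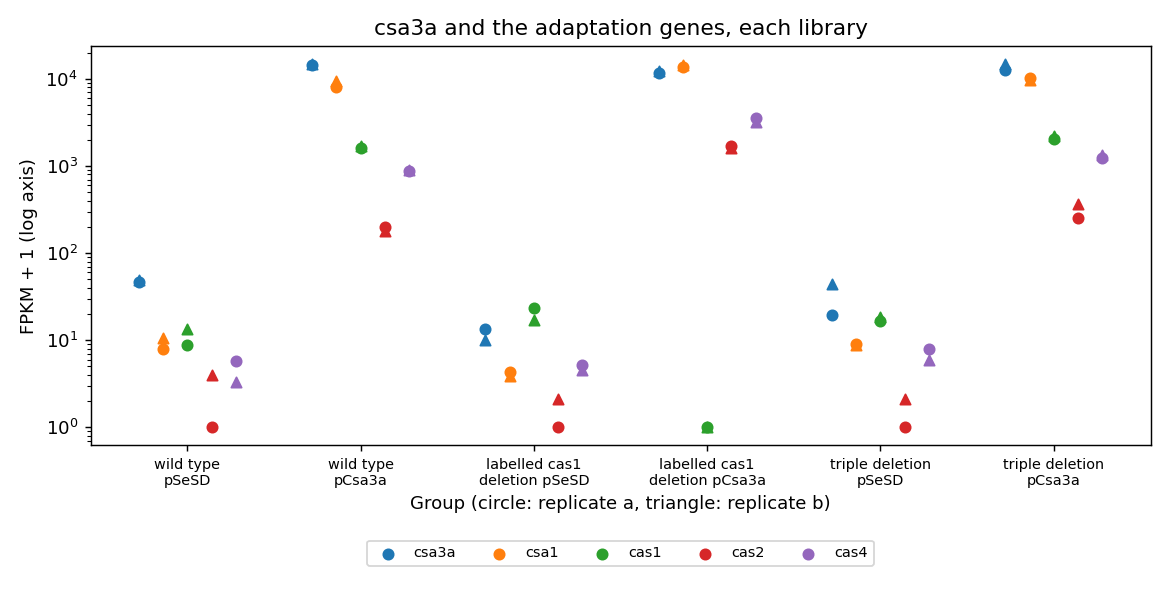
FPKM + 1 on a log axis of csa3a and the 4 adaptation genes in each library (circles, replicate a; triangles, replicate b) of the 6 groups. With pCsa3a all of these genes lie far above the pSeSD libraries except cas1 in the libraries labelled cas1 deletion with pCsa3a, which is at 0, against 22.5 and 15.9 FPKM in those labelled cas1 deletion with pSeSD; the 3 strains come from separately normalized tables.

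In wild type, pCsa3a was accompanied by a very large rise of the adaptation genes, which encode the proteins that acquire new spacers. csa1 (SiRe_0760, RefSeq symbol cas4a) went from 8.20 ± 1.80 to 8792 ± 925 FPKM (log2 fold change 9.91 ± 0.14 SE, adjusted p = 1.12e-12 by limma). cas1 rose 163-fold and cas4 (SiRe_0763) 250-fold in mean FPKM. cas2 (SiRe_0762) had only 2 reads in the pSeSD libraries against 345 with pCsa3a, a ratio of 122 with an exact 95% interval of 33.6 to 1010 that covers counting error only. All 6 members of the adaptation list rose, and all 6 did when adjusted over the list alone. Among them were SiRe_1245 and SiRe_1994, a pair of cas4 genes outside this locus, with log2 fold changes of 1.42 and 0.86. By the list test the adjusted p was 8.99e-05, and adjusted p = 0.0768 with an estimated correlation.

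The genes of the type I-A interference complex, which cleaves invading DNA, rose as well. All 6 list members were higher over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.61. csa5 (SiRe_0766) rose from 889 ± 37.2 to 3849 ± 252 FPKM, and cas3 from 15.9 ± 0.107 to 57.8 ± 2.04 FPKM. The neighbouring HD-domain gene SiRe_0770 rose by 1.58 ± 0.18 on the log2 scale and the second csa3 gene, SiRe_0765, by 0.96 ± 0.14. The list test gave an adjusted p of 0.00182, and adjusted p = 0.272 with an estimated correlation. Of the 11 members of the type III-B Cmr list, which target RNA, none passed the limma threshold in wild type (median log2 fold change 0.19), and none did by limma-voom on recovered reads.

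Genes of DNA import, replication and repair also changed in wild type. Of 13 genes of DNA import and type IV pili, 10 rose and 2 fell (11 and 2 adjusted over the list alone). They included cedA1 (SiRe_1316), part of the crenarchaeal system for importing DNA, at 1337 ± 111 against 4580 ± 536 FPKM with pCsa3a, and the pilin gene upsA (SiRe_1881), which rose 2.60-fold. The 2 that fell, SiRe_0180 and SiRe_0181, are annotated as type II secretion system proteins. The 7 genes matched by the replication keywords are called replication genes here, although a match does not establish that role. Of these, 6 rose, with the same number adjusted over the list alone. These were the 2 genes annotated as parts of family B polymerases, SiRe_0614 (5.22-fold) and SiRe_0615 (3.56-fold), as well as SiRe_0459 with a polymerase beta domain (4.12-fold), ssb, mcm and SiRe_1352, a peptidase annotated as a modulator of gyrase; the topoisomerase I gene SiRe_1176 fell. The list tests gave an adjusted p of 0.0371 for both lists, and with an estimated correlation adjusted p = 0.534 for import and adjusted p = 0.419 for replication. Of 9 repair genes 6 rose, led by the repair ATPase SiRe_0649 (22.4 ± 1.78 to 126 ± 0.901 FPKM), but after centring each library on its median only 2 rose and 2 fell, and the list did not pass its test (adjusted p = 0.311). Product names come from the authors' tables of called genes for 5 of the 7 replication genes and 5 of the 13 import genes, so these lists are partly chosen on these samples and their direction is not independent evidence.

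Other large rises in wild type were in features listed at 0 in both pSeSD libraries, the noncoding feature SiRe_nc0055, SiRe_1102 and SiRe_1478, at 27.1, 23.4 and 10.3 FPKM on average with pCsa3a. For SiRe_1102 this rested on few reads, a mean count of 7.43 with pCsa3a in the authors' deposited table. SiRe_0340, a subunit of pyruvate ferredoxin oxidoreductase, rose from 2.46 ± 0.344 to 62.8 ± 4.12 FPKM, and dps (SiRe_0453), a ferritin-like protein gene, from 106 ± 7.30 to 1413 ± 241 FPKM. Among the lowest genes were SiRe_0001 (121 ± 20.1 to 19.2 ± 1.92 FPKM), the methyltransferase gene SiRe_1791, the neighbours SiRe_0528 and SiRe_0529, SiRe_0816, the tRNA features SiRe_t0035 and SiRe_t0037 and the noncoding feature SiRe_nc0015. The sugar-binding protein genes glcS (SiRe_2180, log2 fold change -1.04) and SiRe_2190 (-0.93) also fell, although leaving out single libraries ended both calls. Of the structural RNA measured in this table, the RNase P RNA gene rnpB fell by 0.43 on the log2 scale and 23S rRNA was at -0.25 (adjusted p = 0.16). After centring both were lower (-0.69 and -0.52, adjusted p = 0.0317 and 0.039), so a difference in RNA depletion between the plasmids is not ruled out.

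In total 940 of 2697 features passed an adjusted p of 0.05 in wild type, 791 higher and 149 lower. The median log2 fold change of all features was 0.23, and after centring the split was 445 higher and 488 lower, so small rises are relative to this shift. At least 2-fold changes numbered 293 higher and 8 lower, or 197 and 28 after centring. Leaving out 1 library gave 511 to 653 features.

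**Figure D2:**
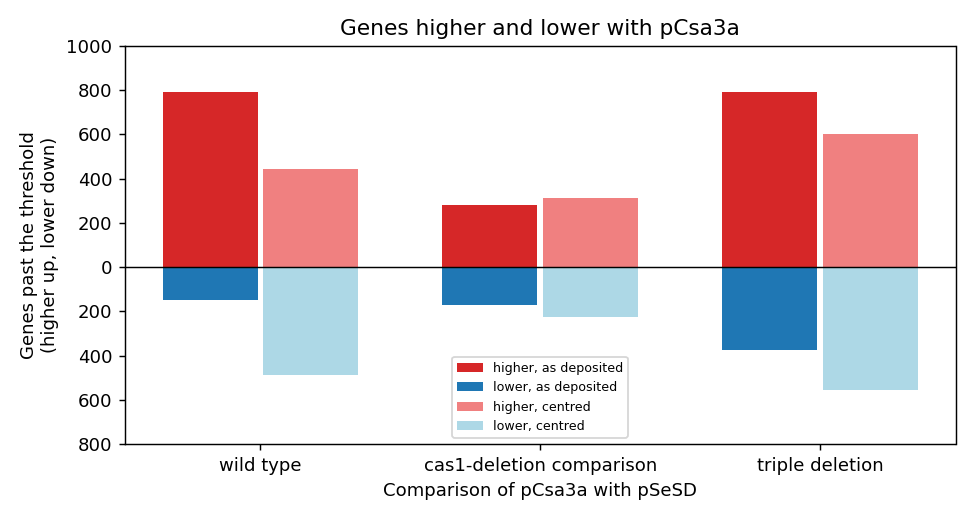
Number of features past an adjusted p of 0.05 (vertical axis, higher with pCsa3a above 0 and lower below) in the 3 comparisons, with FPKM as deposited and after centring each library on its median. In wild type the split moved from 791 higher and 149 lower to 445 and 488.

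In the cas1-deletion comparison, where direction depends on the doubtful libraries labelled cas1 deletion with pSeSD, csa1, cas2 and cas4 rose more steeply than in wild type, while the separate cas4 gene SiRe_1245 did not pass the threshold (-0.15, adjusted p = 0.775). csa1 rose from 3.12 ± 0.318 to 14210 ± 501 FPKM (log2 fold change 11.76 ± 0.14, adjusted p = 1.63e-13 by limma), and cas4 880-fold. cas2 had 1 read in the pSeSD libraries and 2729 with pCsa3a, a ratio of 2880 with an exact 95% interval of 516 to 114000. cas1, at 0 reads against 107, was at least 33.8-fold lower with pCsa3a, taking 3 reads over the group as the floor. Of the 6 adaptation genes 4 rose and 1 fell (the same adjusted over the list alone; list test adjusted p = 0.0274, and adjusted p = 0.478 with an estimated correlation).

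The interference genes did not rise there. None of the 6 passed the threshold upwards, their median log2 fold change was -0.25, and csa5 was at 749 ± 71.1 and 789 ± 21.4 FPKM. cas6 (SiRe_0772) fell by 0.79 ± 0.22 on the log2 scale, a call that ended without replicate a of the pCsa3a libraries (adjusted p = 0.275) and without either pSeSD library. No Cmr gene passed the limma threshold, nor by limma-voom. Of the replication genes 6 of 7 rose, with log2 fold changes of 1.88 for SiRe_0459, 1.56 for SiRe_0614 and 1.07 for ssb (list test adjusted p = 0.0108, and adjusted p = 0.651 with an estimated correlation). Of the import and pili genes 4 rose and 2 fell, and the list did not pass its test (adjusted p = 0.404). The repair list had 4 of 9 higher (3 after centring) and did not pass its test (adjusted p = 0.29), with SiRe_0649 at 2.27 ± 0.19.

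Among the other genes with the largest changes, the IS607 transposase gene SiRe_2296 rose 14.1-fold, a gene that may share reads with near-identical copies, and the unidentified feature Novel00011 was listed at 0 in both pSeSD libraries and at 1807 ± 68.6 FPKM with pCsa3a. The features sRNA00012, sRNA00016 and sRNA00017 rose 12.4-fold, 10.7-fold and 9.42-fold, and sRNA00014 was listed at 0 in the pSeSD libraries. The sugar transporter permease genes glcU (SiRe_2178) and glcT (SiRe_2179) fell by 1.40 and 1.32 on the log2 scale, as did SiRe_2182, SiRe_2663, SiRe_0679, SiRe_2135, SiRe_2653, SiRe_2654 and Novel00028. In total 453 of 2635 features passed, 281 higher and 172 lower; quantile normalization gave 281 and 260. Leaving out 1 library reduced the total to between 166 and 225.

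In the triple deletion the adaptation genes rose as well. csa1 went from 7.94 ± 0.0884 to 10010 ± 502 FPKM (log2 fold change 10.13 ± 0.14, adjusted p = 8.61e-13 by limma), cas1 rose 128-fold and cas4 216-fold. cas2 had 1 read against 588, a ratio of 598 with an exact 95% interval of 107 to 23700. All 6 adaptation genes rose (6 adjusted over the list alone, 5 after centring; list test adjusted p = 3.79e-04, and adjusted p = 0.103 with an estimated correlation). Of the 5 interference genes present, 3 rose (2 after centring). csa5 rose from 2604 ± 248 to 4704 ± 83.9 FPKM, cas7a (SiRe_0767) by 0.48 ± 0.11 and cas5a (SiRe_0768) by 0.41 ± 0.14 on the log2 scale, and the last 2 calls ended in the fit of the compared groups alone (adjusted p = 0.0559 and 0.0996). cas6 was at -0.01 ± 0.22. The interference list did not pass its test (adjusted p = 0.476). Of 9 Cmr genes, cmr4 (SiRe_0602) rose by 0.51 on the log2 scale and none did after centring or adjusted over the list alone.

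Of the import and pili genes 10 rose and 2 fell in the triple deletion (8 and 2 after centring), and of the replication genes 6 of 7 rose, but neither list passed its test with FPKM as deposited (adjusted p = 0.14 and 0.0606). After centring the replication list passed (adjusted p = 0.0495), as it did for the mean over the hosts (0.036, against 0.0572 as deposited), but with an estimated correlation it had adjusted p = 0.64 and 0.524. SiRe_0649 rose 7.62-fold. Of the 9 repair genes 5 rose, but only 2 after centring, and the list did not pass its test (adjusted p = 0.272). SiRe_2296, SiRe_0339, SiRe_0340, Novel00011 and sRNA00014 were among the 10 with the largest rises. The largest fall was in SiRe_0383, which has no product name here (479 ± 339 to 59.5 ± 9.07 FPKM), and several of the next were in genes annotated for sugar or peptide transport. glcS fell from 11060 ± 5823 to 2046 ± 669 FPKM, SiRe_2190, a maltose-binding protein gene, from 1443 ± 826 to 213 ± 34.1 FPKM, and glcU, glcT, SiRe_2186, SiRe_2187, SiRe_2188, SiRe_2469 and SiRe_0974 fell as well. Of 56 transporter genes 10 rose and 18 fell, and the list did not pass its test (adjusted p = 0.0506; 0.0491 after centring, and adjusted p = 0.64 with an estimated correlation). The 2 pSeSD libraries of this strain differed more than any other pair, with a chi-square per degree of freedom of 54.2 against 5.92 to 9.29 elsewhere.

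In total 1166 of 2635 features passed in the triple deletion, 794 higher and 372 lower, with a median log2 fold change of 0.19; after centring the split was 600 and 553. A fit on the compared groups alone called 672, and leaving out replicate b of the pCsa3a libraries 699.

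**Figure D3:**
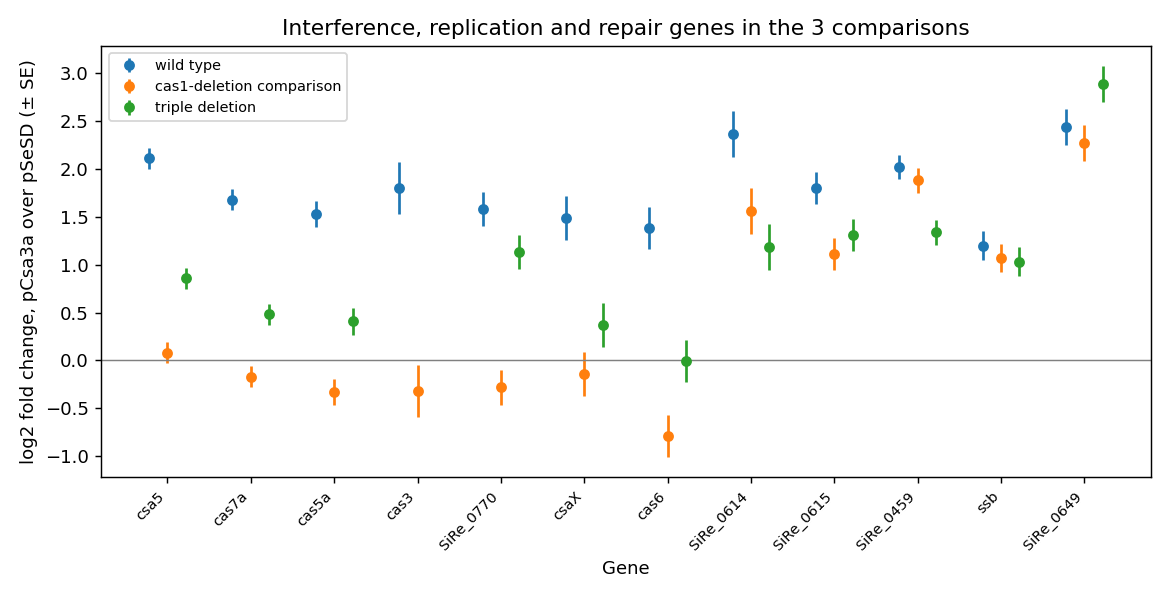
Log2 fold change of pCsa3a over pSeSD (± SE, on the log2(FPKM + 1) scale) of interference genes and neighbours, genes of the replication keyword list and the repair ATPase SiRe_0649 in the 3 comparisons (cas3 is deleted in the triple deletion). The interference genes lie between 1.38 and 2.11 in wild type and near or below 0 in the cas1-deletion comparison, whose pSeSD libraries are of doubtful label.

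Whether the response differed between hosts was tested by the difference of the 2 fold changes. All 6 interference genes changed less in the cas1-deletion comparison than in wild type, with csa5 at -2.03 ± 0.15 (adjusted p = 4.30e-05 by limma), cas7a at -1.85 and cas6 at -2.16. csa1 (1.85 ± 0.20), cas4 (1.79), cas2 (3.59) and csa3a (1.76) changed more. For csa3a this rests on the doubtful pSeSD libraries, at 12.6 and 9.1 FPKM against 46.2 and 47.8 in wild type. With pCsa3a, csa3a was not higher than in wild type (11831 and 12299 against 14346 and 14822 FPKM, in separately normalized tables). In total 230 of 2582 features differed, 24 upwards and 206 downwards, and 66 and 107 after centring; leaving out 1 library gave 79 to 164. In the triple deletion csa5 (-1.26 ± 0.15), cas7a (-1.20), cas5a (-1.12), cas6 (-1.39) and csaX (-1.12, adjusted p = 0.0497, and 0.0536 after centring) also changed less than in wild type, while csa1 (0.22 ± 0.20, adjusted p = 0.493) and csa3a (0.64 ± 0.40, adjusted p = 0.309) did not pass. dps rose less there than in wild type (-2.75 ± 0.29), and the ribosomal protein genes SiRe_1252 and SiRe_1606 and the Cbf5 gene SiRe_1607 had higher log2 fold changes than in wild type (by 1.90, 1.05 and 1.09). In total 315 differed from wild type, 96 upwards and 219 downwards, or 236 and 182 after centring, and between the triple deletion and the cas1-deletion comparison 341 differed, 225 and 116, or 169 and 190 after centring. These 2 counts are not steady, since leaving out 1 library gave 41 to 649 and 78 to 795.

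Averaged over the 3 hosts, csa1 (10.60 ± 0.08), csa3a (9.04 ± 0.16), cas4 (8.22 ± 0.13), cas2 (8.15 ± 0.33) and the transposase gene SiRe_2296 (3.46 ± 0.14) had the highest log2 fold changes. cas1 was at 3.28 because it fell in the cas1-deletion comparison, and at 7.08 without that comparison. The lowest were glcU (-1.43), glcS (-1.42), SiRe_2190 (-1.39), glcT (-1.38) and SiRe_0001 (-1.32). Their order depends on the cas1-deletion comparison, in which the log2 fold change of SiRe_0001 was 2.46 above that in wild type. Of 2582 features 1337 passed, 919 higher and 418 lower, or 687 and 725 after centring. Without the comparison that holds the doubtful libraries, an alternative chosen after seeing the data, 1350 passed. Among the features tested in all hosts, 176 were higher in all 3, where independent calls would share 23.1, and 23 were lower, against 1.3. After centring, 128 were higher in all 3, against 10.9, and 83 lower, against 8.5. Wild type and the triple deletion alone, whose labels are not in doubt, shared 434 higher and 67 lower, against 225.5 and 19.6. After centring that pair shared 244 higher and 253 lower, against 95.8 and 99.3, so shared rises no longer outnumbered shared falls. The 3 comparisons share no libraries, but the fit gave each gene 1 spread over all 12 libraries. Calls of a gene are therefore not independent between hosts, and the excess over the expected counts may be overstated. 39 genes were at least 2-fold higher in all 3. Of these, 38 were still higher past the adjusted p threshold in all 3 after centring, where at least 2-fold was not required again (ssb was at 0.96 in the centred mean). The 39 include SiRe_0649, SiRe_0614, SiRe_0615, SiRe_0459, ssb, the thioredoxin gene trxA and the HEPN-domain gene SiRe_0924.

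The remaining lists, tested on the mean over the hosts, did not pass. Among cell division genes 3 of 6 rose and 2 fell. The chromatin protein list had 2 higher and 2 lower of 6, and cren7 (SiRe_1111) and sul7s (SiRe_1983), which encode small DNA-binding proteins, fell by 0.81 and 0.55 on the log2 scale. For toxin-antitoxin genes the counts were 11 higher and 4 lower of 17, for transposases and integrases 4 and 1 of 6, for transcription machinery 2 and 2 of 6 and for transcriptional regulators 13 and 13 of 33. Ribosomal protein genes gave 4 and 4 of 11, aminoacyl-tRNA synthetases 5 and 0 of 5, and chaperones and proteasome 5 and 1 of 9, with the thermosome gene thsB (SiRe_1716) and the prefoldin gene SiRe_1279 higher. Respiratory chain genes gave 4 and 7 of 19, central carbon metabolism 5 and 3 of 11, amino acid biosynthesis 18 and 3 of 33, nucleotide metabolism 7 and 4 of 13 and transporters 20 and 18 of 56. After centring the balance moved towards lower genes in several lists, with 14 and 8 for amino acid biosynthesis, 7 and 6 for nucleotide metabolism, 17 and 27 for transporters, 4 and 3 for chaperones and proteasome and 2 and 3 for both cell division and chromatin proteins. It was 2 and 4 for transcription machinery, 12 and 17 for transcriptional regulators, 4 and 5 for ribosomal protein genes and 4 and 9 for respiratory chain genes. The balance turned over for transporters and cell division only, and lists with equal counts came out lower. The list of all CRISPR-associated genes, which overlaps the CRISPR lists above, had 16 of 28 higher and passed (adjusted p = 0.00589, and adjusted p = 0.524 with an estimated correlation). The archaellum list had no member, the plasmid marker list 1 (pyrE, SiRe_1392) and the structural RNA list 1 in the deletion tables, so these were not tested as lists. That structural RNA member, SiRe_1261, is an rRNA adenine methylase gene matched by the keywords and not a structural RNA. As a single gene pyrE rose by 0.45 in wild type, 1.33 in the cas1-deletion comparison and 0.34 in the triple deletion (log2). After centring, of these only the rise in the cas1-deletion comparison passed (1.32).

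The authors' deposited tables list 380 higher and 374 lower genes in wild type, 381 and 247 in the cas1-deletion comparison and 257 and 239 in the triple deletion. Of these, 375 and 137, 270 and 150, and 256 and 229 were called in the same direction here, and none in the opposite one; after centring the wild-type figures were 340 and 334. In the authors' deposited table csa1 has log2 fold changes of 9.84, 12.18 and 10.10 in the 3 comparisons. The authors' deposited table for wild type also lists SiRe_0390 and SiRe_1102 with a mean count of 0 under pSeSD and of only 7.13 and 7.43 with pCsa3a. For the triple deletion SiRe_2659 (-3.55), SiRe_0974 (-2.10) and SiRe_0384 (-2.02) have the lowest values. For the cas1-deletion comparison the authors' deposited table gives 11.49 for cas2, -1.68 for SiRe_0679 and -1.47 for SiRe_2663, and lists cas1 among the lower genes. In the authors' deposited table for the cas1-deletion comparison the column headers name the wild type as the reference, whereas its log2 fold changes follow the libraries labelled cas1 deletion with pSeSD (correlation across 626 genes, which are not independent replicates, 0.999, against 0.732 for the wild-type pSeSD libraries over 600 genes).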

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

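All tests of explanations in this part were chosen after the results they bear on had been seen.

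Several results differed between hosts by the interaction test. Between the cas1-deletion comparison and wild type 230 features differed. The log2 fold change was higher than in wild type for csa1 (1.85), SiRe_0001 (2.46, which fell in wild type and did not pass here), SiRe_2649 (1.19), SiRe_0193 (1.08), cas4 (1.79), cas2 (3.59) and csa3a (1.76), and lower for cas1 (-11.56), csa5 (-2.03), cas7a (-1.85), SiRe_2663 (-2.93), the transport protein gene SiRe_0137 (-2.01), the cas4 gene SiRe_1245 (-1.57, adjusted p = 0.0739 after centring), cas5a (-1.86), cas3 (-2.12), csaX (-1.63) and cas6 (-2.16). Between the triple deletion and wild type 315 differed, with SiRe_2584 (1.86), SiRe_2625 (1.5), SiRe_1252 (1.90), SiRe_1606 (1.05) and SiRe_1607 (1.09) upwards and dps (-2.75), SiRe_2663 (-2.32), SiRe_2095 (-1.84), csa5 (-1.26), SiRe_2543 (-1.64), cas7a (-1.20), cas5a (-1.12), csaX (-1.12, adjusted p = 0.0536 after centring) and cas6 (-1.39) downwards. Between the triple deletion and the cas1-deletion comparison 341 differed, with cas1 (11.23), SiRe_2625 (2.10), SiRe_2584 (2.49), SiRe_1080 (2.65), Novel00031 (2.43), csa5 (0.78), cas7a (0.65) and cas5a (0.74) upwards, the last 2 with adjusted p = 0.0551 and 0.0691 after centring, and sRNA00015 (-1.75), sRNA00016 (-1.62), sRNA00017 (-1.47), csa1 (-1.63), SiRe_0370 (-1.18) and cas4 (-1.90) downwards. Values for cas1 and cas2 rest on groups at or near 0 reads and depend on the pseudocount. The value for csa3a against wild type rests on its low level in the doubtful pSeSD libraries, not on a higher level with pCsa3a.

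The libraries labelled cas1 deletion with pSeSD held 62 and 45 cas1 reads. Carry-over from pCsa3a libraries with an intact cas1 would have to bring 1.16% of their reads and so 102 FPKM of csa1, but csa1 was at 3.12 FPKM. A deletion leaving part of the gene would show reads in the pCsa3a libraries of the strain too, where 0 were counted. Cells with an intact cas1 remain a candidate explanation, since the lower of the 2 values, 15.9 FPKM, lies within the 7.7 to 17.4 FPKM of the other pSeSD libraries, which come from separately normalized tables. The other value, 22.5 FPKM, lies above all 4 of them. In the same libraries cas3 had 83 and 88 reads, SiRe_0598 had 605 and 559, and SiRe_0894 had 216 and 228. These genes were at 0 reads in the triple deletion, which argues against that host as the only source of these libraries. Whether the cas1 reads come from a wrong label, another strain or a mixed culture stays otherwise open.

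The interference genes rose with pCsa3a in wild type and not in the cas1-deletion comparison. Scaling is argued against, since after centring the median difference over the 6 genes was still -1.70, with a range of -1.91 to -1.38. A pSeSD host other than the cas1 deletion cannot be told apart from an effect of the host: the median log2 fold change in that comparison was -0.25, and no other pSeSD library of the strain was measured. The levels with pCsa3a do not rest on the doubtful pSeSD libraries. With pCsa3a, cas3 was at 12.8 and 15.2 FPKM in the labelled cas1 deletion and at 59.3 and 56.4 FPKM in wild type, in separately normalized tables. Whether cas3 rose in the labelled cas1 deletion does rest on them. An effect of losing cas1 itself stays among the open explanations, untested. The triple deletion, in which cas1 was expressed, also changed less than wild type in csa5 (-1.26), cas7a (-1.20), cas5a (-1.12) and cas6 (-1.39), so a smaller fold change was not limited to the cas1-deletion comparison. The levels differed, however, in the separately normalized tables. csa5 went from 2604 to 4704 FPKM in the triple deletion, from 889 to 3849 in wild type and from 749 to 789 in the cas1-deletion comparison. The fold changes alone do not show that the 2 deletion hosts responded alike.

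In wild type more features were higher than lower with pCsa3a. The 10 most abundant genes, which include the rRNA features SiRe_r0001 and SiRe_r0002, took 33.1% and 33.2% of reads under pSeSD and 27.3% and 27.0% with pCsa3a. Taking these 10 genes out of the totals moved the median log2 fold change from 0.23 to 0.11, which lies between the bounds set for and against this explanation. Part of the shift could therefore come from these genes, and the rest cannot be told apart from a broad change in relative levels. Because rRNA is among the genes taken out, this step does not separate a difference in RNA depletion from changes of the other abundant genes. No biological explanation was tested.

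For the mean over the hosts, 1 of 100 drawn splits of the libraries within the hosts, the real one, gave as many as its 1337 features, and the highest of the others gave 817. Chance can be excluded for that count only if the libraries of a group are separate cultures, which the labels do not state; if they are repeats of 1 culture, chance differences between cultures stay open. The highest other split exchanged the plasmid labels of the cas1-deletion comparison only. No single host has groups of 3, so no such count exists for the other comparisons.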

How the results depend on the processing

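Of 510 single genes in a comparison, 8045 of 8506 values under the alternatives kept direction and side of the threshold, 387 lost the call, 73 gained it and 1 turned: cmr6 (SiRe_0893) in the mean over the hosts, at -0.24 with quantile normalization. These 510 include genes named for their large changes or small p-values, so this stability need not hold for all features. A fit on the compared groups alone called 672 features in the triple deletion, and 375, 198 and 218 for the differences cas1 deletion minus wild type, triple deletion minus wild type and triple deletion minus cas1 deletion. Quantile normalization gave 139 for the first of these and eBayes without trend 227 for the last. Of 11 list calls, 0 held with an estimated correlation. Of the 1878 entries in the authors' 6 lists, where a gene can appear in more than 1 comparison, 474 had an absolute log2 fold change of at least 1. The cause of these changes was not tested. Leaving out 1 library, the lone sample being assumed to vary like the other groups, gave 511 to 653 in wild type, 166 to 225 in the cas1-deletion comparison, 699 to 1376 in the triple deletion, 1160 to 1524 for the mean, and 79 to 164, 41 to 649 and 78 to 795 for the 3 differences in the order above; the largest came without replicate a of the triple-deletion pSeSD libraries (649 and 795), the noisiest pair, and the smallest without replicate b of the wild-type (79 and 41) or triple-deletion pCsa3a libraries (78 and 699).

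With the replicate letter as a replicate block, counts were 927, 417, 1151 and 1321 for the 3 hosts and the mean, and 199, 283 and 321 for the differences. The deviations of libraries with the same letter correlated at -0.009, -0.01 and -0.09 within the 3 hosts, and at -0.097 to 0.137 between groups of different hosts, so no pairing of the plasmids by letter was seen within a host. Limma-voom on recovered reads, chosen after seeing the data, called 890, 612, 1185 and 1405. The contrasts of deletion strains with wild type under pSeSD were not run because the tables were normalized separately. Depth limits the genes with few reads, such as cas2 with 0 to 2 reads per pSeSD library.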

Other observations

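The tests of this part were chosen after the data had been seen. Many of the sRNA features of the deletion tables, whose identity is not given in the sources used here, were higher with pCsa3a. No test of them as a set was run, and in the cas1-deletion comparison the direction rests on pSeSD libraries of doubtful label. Of 24 tested, 15 rose and none fell in the cas1-deletion comparison (16 and 0 after centring), and 19 rose and 1 fell in the triple deletion (17 and 3 after centring). Of the 14 from sRNA00005 to sRNA00018, picked after their values were seen, 13 rose in each, with log2 fold changes of 2.78 to 4.33 and 1.47 to 5.02. Novel00025, the feature with the highest FPKM in these tables, was at 622700 ± 20250 and 400700 ± 79490 FPKM in the triple deletion with pSeSD and pCsa3a (SD, n = 2; log2 fold change -0.65 ± 0.15).

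A hypothesis was that the response beyond the CRISPR genes may be smaller in the cas1-deletion comparison. Over the 1110 other genes called in the triple deletion after centring, which shares no library with the rest, the median change in the direction of the triple deletion was 0.27 and 0.26 in the 2 pCsa3a libraries of the cas1-deletion comparison and 0.38 and 0.33 in those of wild type. The ranges do not overlap, but both libraries of a host are set against the same pSeSD mean, and the pSeSD libraries of the cas1-deletion comparison are of doubtful label, so a smaller response remains a hypothesis.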
